A study of Rattus norvegicus with 2 samples.

How the data were processed

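RNA was profiled by bulk RNA sequencing in 2 cultures of rat oligodendrocyte precursor cells (OPCs), the dividing glial cells that give rise to myelinating oligodendrocytes. Per the labels, 1 culture received amyloid-beta (Aβ) peptide at 1 µM for 2 days and the other received the solvent DMSO, and each gave 1 library. Group membership was taken from the treatment recorded for each sample and from its title. The protocol text about treatment is worded identically for both samples and describes Aβ only, so the time in DMSO rests on that shared text. The labels speak of adult OPCs in the extraction protocol and of developing animals in the design, and both sample titles carry an unexplained P1. The age of the donors was left open here.

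Per the labels' protocols, mRNA libraries were built with a BGI kit from total RNA. The submitters' processing notes name Bowtie2 and the rat build Rnor_6.0. The version of Bowtie2, the quantifier and the annotation release are not given in the sources used here, and neither is the use of strand in counting. The deposited table lists 17202 genes, with 4 values per gene and library. The authors' estimated counts (expected counts) need not be whole. Fractions of this kind arise when a quantifier divides reads that match several transcripts between them, and how this was done here is not given in the sources used here. The authors' TPM values, per the file headers, are scaled to the same total in each library, and the authors' FPKM values are fragments per kilobase of transcript, scaled to library size. A further signal column is named as a normalized read count per the file headers. In both libraries, 100% of its values above 0 equalled the estimated count rounded up and divided by 1 constant for the library (1.00 for Aβ and 0.998 for DMSO), so it was not analysed further.

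Estimated counts summed to 15117102 in the Aβ library and 15019416 in the DMSO library. Fractional estimated counts were listed for 11.9% of genes in each library, and such genes held 14.4% of the counts in each. Counts were rounded to whole numbers for counting intervals and for library factors. CPM values (counts scaled to library size) were computed on effective library sizes from the TMM method of edgeR 4.0.16 in R 4.3.3. A gene was taken as measured at 1 CPM or more in at least 1 library. Its ratio was expressed as log2((CPM in Aβ + 0.5)/(CPM in DMSO + 0.5)), a scale that understates differences of low genes. Ratios without a pseudocount were given with exact 95% Clopper-Pearson intervals, conditional on the sum of both counts. Such intervals cover counting error only.

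With 1 library per group there was no replicate, so no test was run, no p-value was computed and no difference has a replicate check. The rule of size called a gene higher or lower when its log2 ratio was at least 1 in size and its counting interval left out 1. A gene at 0 counts in 1 library was set against a floor of 3 counts in that library. The text names genes by a fixed rule. It takes up to 12 genes with the highest and 12 with the lowest log2 ratio among called genes at 10 CPM or more in the higher library with a symbol that is not a bare identifier, of which 5 and 7 qualified. It adds up to 4 measured members of each list with the largest log2 ratio in size, and a panel fixed in advance (Pdgfra, Cspg4, Olig2, Sox10, Mbp, Mag, Mog, Cnp, Myrf, Il1b, Il6, Tnf, Ccl2, Cxcl10, Nfkbia, Acta2, Myl9, Myh9, Rhoa, Rock1, Rock2, Mki67, Actb and Gapdh). Some genes that the rule takes are not reported here. Genes named outside this rule are marked as such, apart from near-copies given beside a gene that it names.

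There were 25 gene lists and 7 lists of cell type markers. They covered OPC markers, myelin and differentiation, inhibitors of differentiation, inflammation, interferon response, antigen presentation, actomyosin contraction, actin branching, SRF and YAP targets, extracellular matrix, cell cycle, cholesterol and fatty acid synthesis, lipid efflux, unfolded protein, oxidative and heat shock responses, p53 targets, hypoxia and glycolysis, amyloid precursor processing, immediate early genes, growth factors, disease-associated oligodendrocyte genes, housekeeping genes and mitochondrially encoded genes. Marker lists were fixed for astrocytes, microglia and macrophages, neurons, endothelium, fibroblasts and pericytes, Schwann cells and ependyma. The groups, the rule of size, the lists and the first set of alternatives were fixed before the data were examined. Each list was described by the median log2 ratio of its measured members, with a counting interval from 1000 Poisson draws. Its percentile is the percentage of 10000 random lists of the same size, matched on mean level in 20 bins, whose median lay lower. The percentile describes these 2 libraries, and random lists do not carry the shared variation of genes that are regulated together. Mitochondrially encoded genes, Il6, Ccl5 and Cxcl11 were not analysed here.

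Near-copies were found by name. Gene identifiers were looked up in a RefSeq gene table of the assembly GRCr8, used for names only, in which 93.8% of the identifiers matched. Genes with the same name there formed 154 groups, called near-copies here, whose counts were also summed. Sequences were not compared. A group can hold repeated entries of the same gene, such as Ccnj with gene-Ccnj, or entries with unlike symbols, such as Palm2 with Akap2. For groups with a called gene, the ratio of sums was predicted for a change in that gene alone, with its near-copies held at their level in either library, and the prediction nearer to 1 was taken. It counted as visible when the predicted counts had an interval without 1. This comparison and its rule were chosen after seeing the data. The trend of the ratio with effective transcript length (from estimated counts and FPKM) was fitted by lowess with a span of 0.3 over genes with whole counts. Spread beyond counting was taken from genes with whole counts and at least 100 counts over both libraries, as the median squared difference of log ratios over the counting variance, with its SD from 200 bootstrap draws over genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

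The steps were tested on simulated data, with counts drawn for all 17202 genes of the Aβ against DMSO comparison from their observed means and 200 genes altered. The altered genes were taken from those with a mean above a level set higher than the level of measurement. Recovery was therefore not tested for the lowest measured genes. The rule called 94.0% of 50 genes altered 2.5-fold and all of the 50 genes altered 4-fold and the 50 altered 8-fold, in the right direction. It called 0 of 50 genes altered 1.5-fold, which lies below the threshold by construction, and 11 of 13303 unaltered genes. In 20 simulated pairs with no difference, counting intervals held the true ratio for 95.5% of genes above a minimum mean count, and between 1 and 11 genes were called. Coverage was not assessed for genes with fewer counts. The squared difference over the counting variance averaged 1.00 there and reached at most 1.05. Of 50 unaltered lists, 86.0% had percentiles between 5 and 95.

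Alternatives were total counts, DESeq2 1.42.0 size factors, no filter, a filter of 10 CPM, pseudocounts of 0.1 and 5, thresholds of 1.5-fold and 4-fold, the TPM, FPKM and upper-quartile-scaled TPM values, and random lists with no matching on level. Added after seeing the data were genes with whole counts alone, near-copies summed, and removal of the length trend.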

Results

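Transcript levels were measured by RNA sequencing in primary rat OPCs, the precursors of myelin-forming oligodendrocytes, after 2 days with 1 µM amyloid-beta (Aβ), the peptide that forms plaques in Alzheimer's disease, or with the solvent DMSO. Each condition was represented by 1 library, with 15117102 estimated counts for Aβ and 15019416 for DMSO. A count above 0 was listed for 16580 genes with Aβ and 16568 with DMSO, and 13505 genes were measured at 1 CPM or more in at least 1 library. Both libraries had the same 10 most abundant genes, headed by the elongation factor Eef1a1, the lipid desaturase Scd2 and Vim (vimentin), named after their values were seen, and the 10 took 4.50% of counts with Aβ and 4.53% with DMSO. Ratios are given as Aβ over DMSO, with 95% intervals that cover counting error only. There were no replicates, so the values compare 2 libraries. TPM raised the ratios, with a median log2 ratio of 0.036 over all genes, and list medians given with TPM carry that shift.

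The comparison addresses whether Aβ alters genes of oligodendrocyte differentiation, of inflammation and of cell contraction, the topics of the series. Most genes were at closely similar levels in both libraries, and the list medians of those 3 groups lay close to 0. Markers of OPCs were slightly higher with Aβ. Pdgfra, the receptor for the OPC mitogen PDGF-A, had 995 CPM against 923 CPM with fractional counts (ratio 1.08, interval 1.05 to 1.10). Cell cycle genes were slightly lower, with Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, at a ratio of 0.833 (0.760 to 0.912). Myelin, inflammatory and actomyosin genes had median log2 ratios of -0.055, 0.020 and -0.0012. Gene lists with medians further from 0 than OPC markers (0.085) were antigen presentation (0.091), p53 targets and cell death (-0.095) and disease-associated oligodendrocyte genes (-0.18).

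Across genes, which are not independent replicates, log2 CPM of the 2 libraries had a correlation of 0.992. Of the 11726 measured genes with whole estimated counts, 90.6% lay within 1.2-fold and 98.7% within 1.5-fold. The counting interval lay wholly within 1.5-fold for 80.1% of measured genes. No gene with whole counts at 50 CPM or more (4585 genes) lay beyond 1.5-fold, and the furthest had a log2 ratio of 0.32. Differences were larger than counting alone gives. The squared differences were 1.56 times the counting variance (bootstrap SD 0.033), which corresponds to a spread beyond counting of 3.68% per gene.

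**Figure D1:**
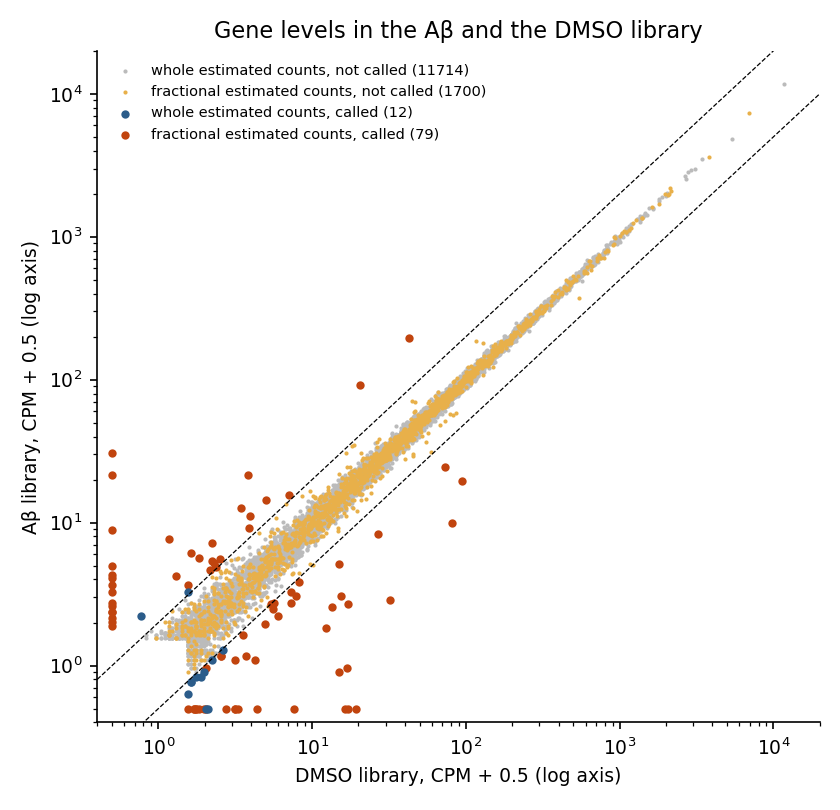
CPM + 0.5 of each measured gene in the DMSO library (horizontal, log axis) and in the Aβ library (vertical, log axis), with dashed lines at 2-fold; colours separate genes with whole and with fractional estimated counts, and larger points are the 91 called genes. Of these, 79 have fractional counts, and the 12 with whole counts sit at the low end, at 2.78 CPM or less.

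The rule of size called 91 genes, or 0.674% of those measured, of which 36 were higher with Aβ and 55 lower. Fractional counts, which arise when a quantifier divides reads that match several transcripts, were listed for 86.8% of called genes and for 13.2% of measured genes. Among genes with whole counts, 2 were called higher and 10 lower, and none of the 12 exceeded 2.78 CPM. In 20 simulated pairs with no difference but counting, between 1 and 9 genes with whole counts were called. The 2 higher ones, named after their values were seen, were Btn2a2, a butyrophilin (42 against 16 counts, ratio 2.60, 1.43 to 4.96), and LOC102548541 (26 against 4 counts, ratio 6.45, 2.24 to 25.4). With a filter of 10 CPM, 9 genes were higher and 15 lower.

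Of the called genes with a symbol and at least 10 CPM, 5 were higher. Rabif, a Rab GTPase regulator, had 459 counts with Aβ and 0 with DMSO. It was 152-fold higher against a floor of 3 counts, and the lower interval limit of its ratio was 123. The gene-Ccnj entry of the cyclin J gene had a ratio of 6.33 (4.69 to 8.71), and Wbp11, a splicing factor, 4.60 (4.05 to 5.23). Pak2, a kinase downstream of Rac and Cdc42, stood at 3.07 (2.23 to 4.28) and Dr1, a transcriptional repressor, at 3.05 (2.31 to 4.07). The 7 lower genes were Vwa5a at 0.0276 (0.010 to 0.0610), Triap1 at 0.0283 (0.0113 to 0.0593), RT1-DMa, a subunit of the MHC class II peptide loader, at 0.112 (0.0668 to 0.178), the kinase Sbk1 at 0.116 (0.0965 to 0.138), Wbp11l1 at 0.201 (0.177 to 0.229), Ccnj at 0.295 (0.238 to 0.363) and Myh9l1 at 0.330 (0.292 to 0.372). All of these genes had fractional counts. So did Pdgfra, Mki67, Gapdh, Fth1, Chmp2a, Mx1, Atf3 and Myh9, which are named elsewhere in the text and were not called.

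Several called genes had a near-copy that differed the other way. Wbp11 and Wbp11l1 together had 1668 counts with Aβ and 1712 with DMSO, a ratio of 0.966 (0.903 to 1.03). Both cyclin J entries summed to 437 and 447 counts (0.970, 0.848 to 1.11), and Rabif with RGD1563962 to 495 and 475 (1.03, 0.910 to 1.17). Triap1 with gene-Triap1 summed to 524 and 518 counts (1.00, 0.887 to 1.14). Myh9, the heavy chain of nonmuscle myosin IIA, had a ratio of 1.40 (1.32 to 1.49) as listed, while Myh9 and Myh9l1 together had 3096 and 3027 counts (1.01, 0.965 to 1.07). The entry listed as Myh9 carries the gene identifier 100911597, and the entry listed as Myh9l1 carries 25745, which the RefSeq table names Myh9. Near-copy groups with a called member numbered 12, and 1 of them lay at least 1.5-fold apart after summing. It was Oas1a with Oas1g, interferon-induced oligoadenylate synthetases, with 2 counts against 19, named after its value was seen. In the rest the summed ratio lay between 0.951 and 1.12. Vwa5a, RT1-DMa, Sbk1, Pak2 and Dr1 had no near-copy of the same name to sum with.

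**Figure D2:**
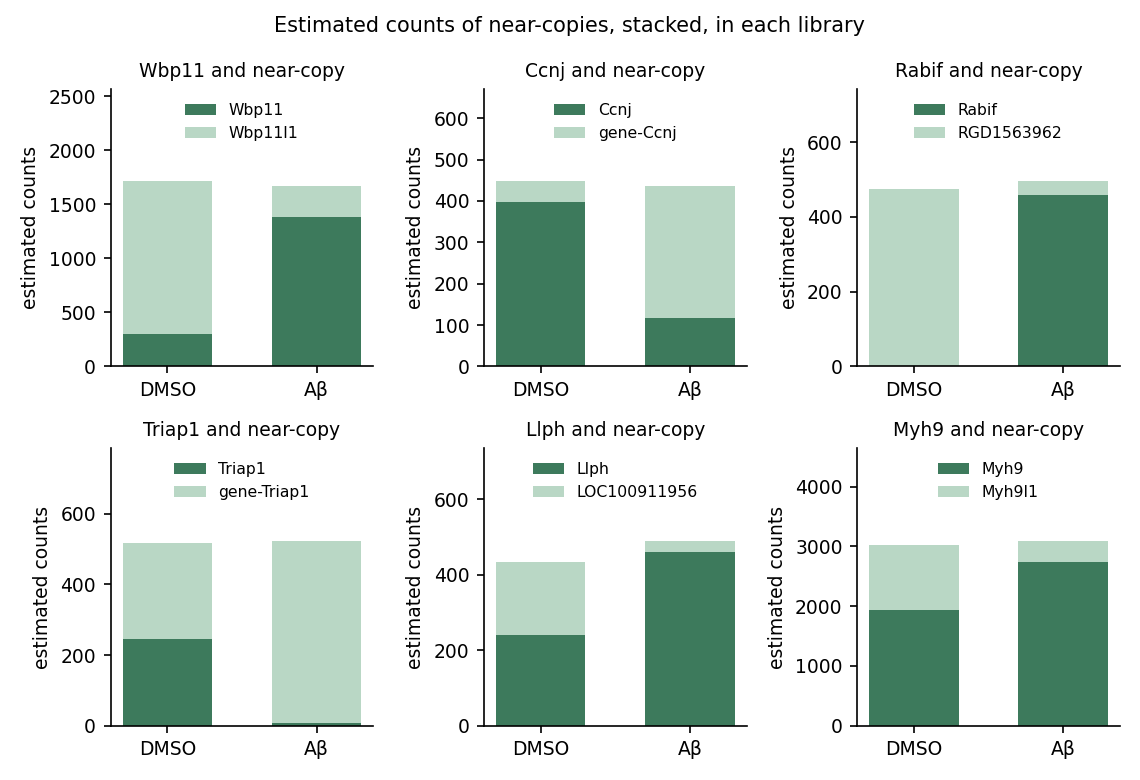
Estimated counts (vertical, linear axis from 0) of 6 pairs of near-copies in the DMSO and the Aβ library, stacked, with 1 library per bar. The division between the copies differs between the libraries while the stack differs little, as for Wbp11 with Wbp11l1 at 1712 counts in DMSO and 1668 in Aβ. The pairs drawn are a selection. Oas1a with Oas1g, whose sum does differ (19 counts in DMSO and 2 in Aβ), is not drawn.

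Among OPC and oligodendrocyte genes, 16 of 21 measured OPC markers had a ratio above 1 and 5 below. Their median log2 ratio was 0.085 (counting interval 0.025 to 0.11), at percentile 100 of random lists. In alternatives chosen after seeing the data, the median was 0.049 with the length trend removed (percentile 99.7) and 0.038 with whole counts alone. The furthest members were Matn4 at a ratio of 0.620 (0.407 to 0.935), Gpr17, a receptor of committed precursors, at 1.17 (1.10 to 1.25), Cacng4 at 1.16 (1.01 to 1.34) and Xylt1 at 1.16 (1.09 to 1.24). Cspg4, the NG2 proteoglycan, had a ratio of 1.06 (0.977 to 1.15). Both lineage transcription factors of the panel were near 1, with Olig2 at 1.01 (0.969 to 1.05) and Sox10 at 0.995 (0.946 to 1.05).

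Of 28 measured genes of myelin and differentiation, 13 lay above 1 and 15 below. Their median log2 ratio was -0.055 (-0.069 to 0.042, percentile 1.28), 0.011 with no filter on level and -0.0025 with TPM. Counting intervals lay wholly above 1 for 5 members and below 1 for 2, and wholly within 1.5-fold for 23. Mbp, a structural myelin protein, was at 20.9 TPM against 23.6 TPM (ratio 0.901, 0.780 to 1.04). Mog had a ratio of 1.14 (0.989 to 1.31), Mag 1.36 (0.806 to 2.32) from 37 and 27 counts, and Cnp 1.05 (1.02 to 1.08). Myrf, the master transcription factor of myelination, stood at 0.932 (0.841 to 1.03). The lowest members were Gpr37 at 0.445 (0.212 to 0.883) from 13 and 29 counts and Aspa at 0.661 (0.432 to 1.00), and Fa2h, which hydroxylates myelin lipids, stood at 1.22 (0.945 to 1.58). Inhibitors of differentiation had a median of 0.040 (-0.034 to 0.084, percentile 91.9), with 12 of 21 above 1. The furthest of these were Smad7 at 1.25 (0.872 to 1.79), Hes1 at 0.823 (0.642 to 1.05), Hey2 at 1.19 (0.918 to 1.56) and Bmp2 at 0.803 (0.398 to 1.60).

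**Figure D3:**
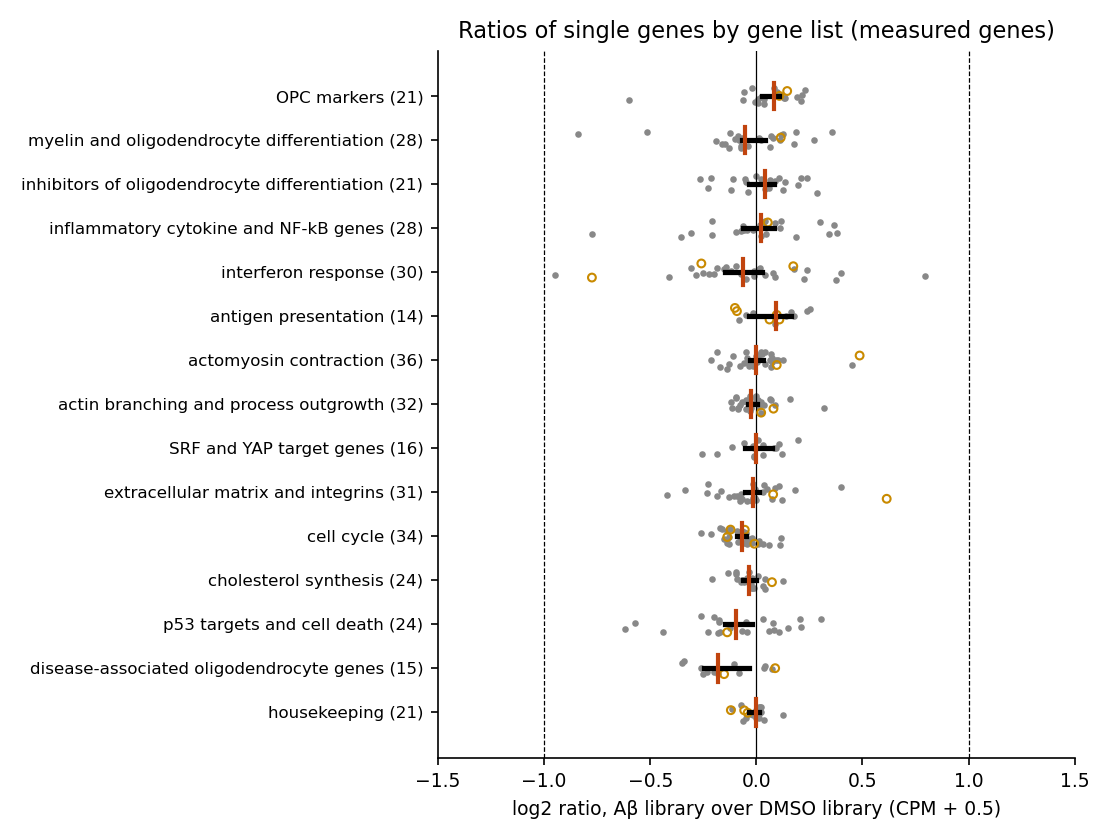
Log2 ratio of Aβ over DMSO (horizontal) for the measured members of 15 gene lists, with the number measured in brackets; filled points have whole and open points fractional estimated counts, red bars are list medians and black bars their 95% counting intervals. No member of the lists drawn reaches the dashed lines at 2-fold, and the medians run from -0.18 to 0.091.

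Inflammatory genes were mostly low, and the counting interval lay wholly within 1.5-fold for 13 of 28 measured members and for 14 of 30 interferon response genes. Of the 28 measured cytokine and NF-kB genes, 16 lay above 1 and 12 below, with a median log2 ratio of 0.020 (-0.064 to 0.082, percentile 71.8). Il1b had 19 counts with Aβ and 18 with DMSO, and Ccl2, a monocyte chemoattractant, 18 and 16. Tnf (7 and 5 counts) and Cxcl10 (3 and 0 counts) were below the level of measurement. Nfkbia, the NF-kB inhibitor that NF-kB itself induces, had a ratio of 1.02 (0.956 to 1.10) at 127 TPM and 121 TPM. The furthest members were Lif at 0.508 (0.285 to 0.880), Rel at 1.45 (0.721 to 3.02), Nfkbie at 1.31 (1.00 to 1.72) and Cd14 at 0.763 (0.551 to 1.05). Interferon response genes had a median of -0.061 (-0.15 to 0.025, percentile 7.93), with 12 of 30 above 1. The furthest members, Ifi44l at 0.390 (0.175 to 0.807), Usp18 at 2.28 (1.04 to 5.37), Mx1 at 0.455 (0.201 to 0.964) and Oas1b at 0.712 (0.441 to 1.14), rested on fewer than 50 counts in each library.

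Antigen presentation genes had a median of 0.091 (-0.035 to 0.16, percentile 96.5), with 9 of 14 above 1. Psmb9 and Tap1, of the immunoproteasome and the peptide transporter, stood at 1.21 (0.915 to 1.60) and 1.19 (0.965 to 1.46), Nlrc5 at 1.16 (0.724 to 1.86) and Tapbp at 1.12 (0.902 to 1.40). Genes described in disease-associated oligodendrocytes had the lowest median of the gene lists, -0.18 (-0.25 to -0.035, percentile 0), with 11 of 15 below 1. It was -0.14 with the filter of 10 CPM and -0.084 with pseudocount 5. Its furthest members were Serpina3n at 0.753 (0.489 to 1.15), Gadd45b at 0.776 (0.582 to 1.03), Anxa5 at 0.832 (0.721 to 0.961) and the alarmin Il33 at 0.837 (0.719 to 0.974).

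Genes of actomyosin contraction divided evenly, with 18 of 36 above 1 and 18 below. Their median log2 ratio was -0.0012 (-0.029 to 0.032, percentile 50.2), and the counting interval lay within 1.5-fold for 33. Rhoa stood at 0.971 (0.942 to 1.00), and its effector kinases Rock1 and Rock2 at 1.03 (0.972 to 1.09) and 0.994 (0.928 to 1.06). Acta2, smooth muscle actin, had 1 count in each library. Besides Myh9, the furthest members were Tagln at 1.47 (0.880 to 2.49) from 40 and 27 counts, Myl9, a myosin regulatory light chain, at 0.846 (0.573 to 1.24) and Mylk, its kinase, at 0.866 (0.592 to 1.26). Genes of actin branching and process outgrowth had a median of -0.027 (-0.038 to 0.0054, percentile 3.68), with Wasf3 at 1.25 (1.09 to 1.43), Kif1b at 1.12 (1.07 to 1.17), Pak1 at 0.921 (0.847 to 1.00) and Stmn1 at 0.923 (0.902 to 0.944). With TPM in place of counts that median was 0.017 and that of actomyosin genes 0.033, beside 0.036 for all genes. SRF and YAP target genes had a median of 0.00052 (-0.052 to 0.073, percentile 45.3), and among their furthest members were Cyr61 at 1.17 (0.769 to 1.79), Nt5e at 0.854 (0.511 to 1.42) and Ptpn14 at 1.09 (0.991 to 1.19). Extracellular matrix and integrin genes had a median of -0.018 (-0.055 to 0.012, percentile 18.6), and of 0.022 with TPM. With the length trend removed, an alternative chosen after seeing the data, it was -0.046 (percentile 0.74), with 20 of 31 below 0. Among these Col1a2 stood at 1.58 (1.19 to 2.11) with fractional counts, Postn at 0.742 (0.646 to 0.853), Lama2 at 1.41 (0.832 to 2.43) and Itga5 at 0.789 (0.692 to 0.899).

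Cell cycle genes were lower with Aβ in 28 of 34 cases. Their median log2 ratio was -0.069 (-0.092 to -0.046), at percentile 0, and the interval lay below 1 for 14 members and above 1 for 0. Ube2c was followed by Mcm3, a subunit of the replicative helicase, at 0.862 (0.804 to 0.925), the mitotic kinase Plk1 at 0.887 (0.831 to 0.948) and the licensing factor Cdc6 at 0.890 (0.732 to 1.08). Mki67, the marker of cycling cells, stood at 0.993 (0.961 to 1.03). With TPM the list median was -0.032, beside 0.036 for all genes. Targets of p53 and cell death genes had a median of -0.095 (-0.15 to -0.020, percentile 0.010), with 15 of 24 below 1. The furthest of these were the necroptosis kinase Ripk3 at 0.610 (0.401 to 0.919), Casp8 at 0.610 (0.351 to 1.04), the death receptor Fas at 0.719 (0.531 to 0.969) and the survival gene Bcl2 at 1.37 (0.636 to 3.05). Immediate early genes had a median of -0.054 (-0.12 to 0.018, percentile 9.66), with Fosl1 at 0.668 (0.484 to 0.917), Arc at 1.41 (0.755 to 2.68), Fosl2 at 1.42 (0.681 to 3.03) and Ier3 at 0.859 (0.700 to 1.05). Neurotrophic and growth factors had a median of -0.028 (-0.19 to 0.041, percentile 31.5), with Pdgfa, the OPC mitogen, at 0.703 (0.507 to 0.969), Cntf at 0.805 (0.577 to 1.12) and Igf1 at 0.847 (0.623 to 1.15).

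Of 24 lipid genes of cholesterol synthesis, 6 lay above 1 and 18 below, with intervals wholly above 1 for 1 and below 1 for 4. Their median was -0.034 (-0.063 to -0.0023, percentile 3.06), and all 24 had intervals within 1.5-fold. Idi1 stood at 0.865 (0.807 to 0.927), Fdft1 at 0.910 (0.861 to 0.963), Nsdhl at 1.09 (1.00 to 1.19) and Hsd17b7 at 0.933 (0.802 to 1.09). Fatty acid synthesis had a median of -0.00081 (-0.014 to 0.051, percentile 55.0), and of 0.039 with TPM, with Me1 at 0.903 (0.842 to 0.967), Acaca at 1.09 (1.02 to 1.17), Elovl7 at 0.887 (0.433 to 1.80) and Elovl1 at 1.06 (0.966 to 1.17). Lipid efflux and droplet genes had a median of 0.029 (-0.025 to 0.10, percentile 86.8). The sterol receptor Nr1h3 stood at 1.66 (1.02 to 2.76) and its target Abcg1, a cholesterol exporter, at 1.23 (1.00 to 1.51). Pnpla2, the triglyceride lipase, stood at 1.89 (1.62 to 2.20) with fractional counts, and Lpl at 0.810 (0.563 to 1.16). Genes of amyloid precursor processing and clearance had a median of 0.040 (0.0073 to 0.064, percentile 99.1), with 15 of 24 above 1. Among them were the gamma-secretase subunits Psen2 at 1.22 (1.01 to 1.48) and Psenen at 1.14 (0.999 to 1.30), the beta-secretase Bace1 at 1.15 (0.986 to 1.33) and the receptor Ager at 0.836 (0.544 to 1.28).

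Stress genes also differed little. The unfolded protein and integrated stress response had a median of -0.0085 (-0.035 to 0.038, percentile 36.8), with Chac1 at 0.803 (0.495 to 1.29), Sesn2 at 1.13 (0.977 to 1.32), Atf3 at 0.882 (0.670 to 1.16) and Ddit4 at 1.11 (1.05 to 1.19). The oxidative stress response had a median of -0.021 (-0.071 to 0.00011, percentile 15.6), with intervals wholly below 1 for 6 of 19 members and above 1 for 0. Gpx1 and the ferritin chain Fth1 stood at 0.874 (0.815 to 0.936) and 0.897 (0.871 to 0.923), Hmox1 at 1.14 (0.951 to 1.37) and Gclm at 0.903 (0.827 to 0.986). Heat shock genes had a median of -0.017 (-0.045 to 0.0091, percentile 30.1) and held 1 called gene, Hspa1a, with fractional counts of 0 and 19.9. Hspa1a was 6.72-fold lower against the floor of 3 counts, and the upper interval limit of its ratio was 0.201. Also in this list, Cryab stood at 0.669 (0.474 to 0.938), Hspb1 at 0.912 (0.813 to 1.02) and Bag3 at 1.08 (0.965 to 1.21). Hypoxia and glycolysis genes had a median of -0.027 (-0.062 to 0.0028, percentile 11.0) and held 1 called gene, the glucose transporter Slc2a3, at 0.392 (0.248 to 0.605) with fractional counts. Adm stood at 0.832 (0.708 to 0.976), Pfkp at 0.928 (0.854 to 1.01) and Aldoa at 0.945 (0.916 to 0.975). Housekeeping genes had a median of -0.0014 (-0.033 to 0.011, percentile 57.0), with Actb at 0.999 (0.983 to 1.02), Gapdh at 0.972 (0.957 to 0.987), Tbp at 1.09 (0.931 to 1.29), Chmp2a at 0.920 (0.849 to 0.996) and Snrpd3 at 0.923 (0.846 to 1.01). With TPM the medians of the oxidative, heat shock, hypoxia and unfolded protein lists lay between 0.016 and 0.027. That of housekeeping genes was 0.027, beside 0.036 for all genes.

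Markers of other cell types were present in both libraries. Bulk RNA cannot tell other cell types in the culture from expression of these genes by OPCs. The highest astrocyte marker was Gfap, named after its value was seen, at 838.5 TPM with Aβ and 792.7 TPM with DMSO. Measured astrocyte markers had a median of 67.7 TPM with Aβ and 63.5 TPM with DMSO (median log2 ratio 0.020, -0.045 to 0.049, percentile 81.5), beside 60.8 TPM and 54.1 TPM for OPC markers. The furthest were Slc39a12 at 0.823 (0.608 to 1.11), Ntsr2 at 1.2 (0.803 to 1.81), Aldh1l1 at 0.883 (0.809 to 0.963) and Agt at 0.944 (0.754 to 1.18). Neuron markers had medians of 22.8 TPM and 22.3 TPM (log2 ratio -0.0080, -0.046 to 0.047, percentile 40.6, and 0.028 with TPM), with the vesicular glutamate transporters Slc17a7 at 0.775 (0.573 to 1.04) and Slc17a6 at 0.886 (0.734 to 1.07), and the neurofilaments Nefm at 1.28 (0.992 to 1.66) and Nefl at 1.12 (0.674 to 1.86). Of 19 microglia and macrophage markers 9 were measured, at medians of 2.35 TPM and 3.27 TPM (log2 ratio -0.11, -0.42 to 0.052, percentile 14.2), with 8 below 1. Among them C1qa stood at 0.520 (0.226 to 1.13), Cd68 at 0.704 (0.388 to 1.26), Itgam at 0.716 (0.323 to 1.55) and Fcer1g at 0.754 (0.392 to 1.43), all from 31 counts or fewer. The 1 above 1 was Lyz2, a lysozyme named after its value was seen, at 1.22 (1.01 to 1.46) with fractional counts, the only member whose interval left out 1.

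Endothelial markers were near the floor, with 5 measured at medians of 0.40 TPM and 0.46 TPM (log2 ratio 0.26, -0.19 to 0.78, percentile 91.0). Vwf stood at 2.38 (1.27 to 4.68) from 36 and 15 counts, Egfl7 at 1.98 (0.846 to 5.01), Flt1 at 0.616 (0.322 to 1.15) and Esam at 1.32 (0.587 to 3.06). Fibroblast and pericyte markers had a median log2 ratio of -0.11 (-0.28 to 0.21, percentile 17.2) over 5 genes, and 0.036 with TPM. Besides Col1a2 these included Thy1 at 0.831 (0.591 to 1.16), Pdgfrb at 0.908 (0.682 to 1.21) and Fbln1 at 1.09 (0.962 to 1.23). Over 4 Schwann cell markers the medians were 63.3 TPM with Aβ and 66.2 TPM with DMSO (log2 ratio -0.077, -0.19 to 0.11, percentile 12.3). These were Prx at 0.918 (0.612 to 1.37), Pmp22 at 0.933 (0.876 to 0.993), Egr2 at 0.961 (0.713 to 1.29) and Sox2, which OPCs also express, at 1.04 (1.00 to 1.09). Of the ependymal markers 1 was measured, Foxj1, at 0.781 (0.568 to 1.07).

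**Figure D4:**
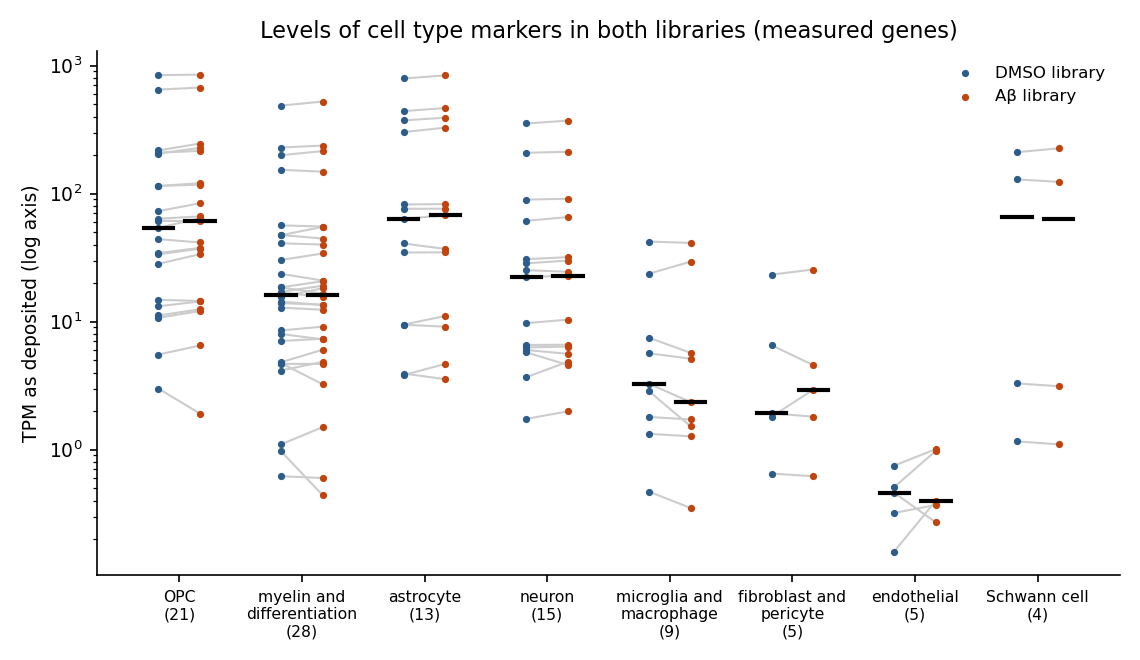
Deposited TPM (vertical, log axis) of measured members of 8 lists in the DMSO library (blue) and the Aβ library (red), with grey lines joining the same gene and black bars at medians; numbers measured are in brackets. OPC, astrocyte, neuron and Schwann cell markers have medians above 20 TPM in both libraries, and endothelial markers below 1 TPM.

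For genes with few counts, such as Mag or Il1b (0.520 to 2.12), the counting interval reached beyond 2-fold. List medians describe these 2 libraries and have no replicate error.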

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

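The alternatives with whole counts alone, near-copies summed and the length trend removed were chosen after seeing the data; the rest were planned. Against 36 higher and 55 lower genes, the filter of 10 CPM gave 9 and 15, pseudocount 5 gave 8 and 16, the 1.5-fold threshold 105 and 129, the 4-fold threshold 18 and 21, and whole counts alone 2 and 10. The first 4 alter the number by construction, through the genes kept, the weight of low genes or the threshold itself, and the last leaves out genes with fractional counts. Under the other 9 alternatives the counts lay between 30 and 51 higher and between 45 and 82 lower. With the authors' TPM, the list medians were 0.12 for OPC markers, 0.033 for actomyosin contraction and -0.032 for cell cycle. The median of all genes was 0.036 with TPM, -0.0016 with FPKM and 0.0075 with upper-quartile-scaled TPM. FPKM values summed to 702073 with Aβ and 721682 with DMSO. TPM scale both to the same total, which raises the ratio of every gene by the same factor. OPC markers stayed above 0 in all alternatives tried (lowest 0.038, whole counts alone) and cell cycle genes below 0, while the myelin list moved to 0.011 with no filter. Against random lists with no matching on level, the percentile was 99.7 for OPC markers, 0.10 for cell cycle and 1.38 for myelin. Over all lists 24 percentiles moved without matching and 6 did not, and among those that moved were interferon response from 7.93 to 0.56, actin branching from 3.68 to 11.3, amyloid processing from 99.1 to 92.9 and microglia from 14.2 to 1.31. Over all lists and alternatives, 339 medians stayed within their counting interval and 14 did not. Summing near-copies turned the log2 ratio of Myh9l1 to 0.021, of gene-Ccnj to -0.044, of Triap1 to 0.0048 and of Wbp11 to -0.049. No other called gene named by the fixed rule changed sign. The called members of the Llph and Selenbp1 groups, named outside it, also did, from -2.40 to 0.16 and from -1.44 to 0.13. No paired analysis was possible because each group had 1 library, and no replicate could be left out. Removing mitochondrially encoded genes from the totals was not run, since they were not analysed here. At this depth the counting interval lay wholly within 1.5-fold for 80.1% of measured genes.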

Other observations

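The tests of explanations below, the genes named in the next paragraph, and Top2a were chosen after the results were seen.

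Among genes with whole counts at 50 CPM or more, the highest ratios were small. Zfp704 stood at 1.25 (counting interval 1.15 to 1.36), Zbed6 at 1.24 (1.14 to 1.36), Msl2, of a histone acetyltransferase complex, at 1.23 (1.10 to 1.37), Cpd, a carboxypeptidase, at 1.22 (1.12 to 1.34) and the nuclear receptor coactivator Ncoa2 at 1.22 (1.10 to 1.36). The lowest were Prmt3, an arginine methyltransferase, at 0.818 (0.743 to 0.900), Cep55, of the abscission step of cell division, at 0.821 (0.743 to 0.907), Lgals1 (galectin-1) at 0.823 (0.752 to 0.900) and Ube2c at 0.833 (0.760 to 0.912). Ribosomal protein genes had a median log2 ratio of -0.048, with 73 of 94 below 1, and of -0.020 after removal of the trend with transcript length. That trend took the median ratio from 0.987 over the 2258 genes with the shortest transcripts to 1.02 over the 2259 with the longest.

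Genes at least 2-fold apart between the libraries were mostly those with fractional counts, listed for 86.8% of called genes against 13.2% of measured genes, so reads shared between near-identical genes may account for many of them, but near-copies could be summed for 15 of the 91, and this left 32 higher and 45 lower. In 8 of 12 near-copy groups, a change in the expression of the called gene alone would move the sum with its near-copies visibly. The interval of the observed sum held that prediction in 1 of the 8 (Oas1a with Oas1g). In the Ccnj, Rabif and Wbp11 groups both members were called, so the outcome was fixed in advance and the sum adds nothing there. For Myh9 and Triap1, and for Llph and Selenbp1, named after their values were seen, the sum argues against a change in the called gene alone. A rule for visibility tried first, which set the prediction against the width of the observed interval, left Oas1a with Oas1g out and gave 0 of 7. In the remaining 4 of the 12 groups the called gene's change alone would leave the sum within its counting interval, so they cannot tell. Near-copies that differed in opposite directions in the cells could give the same sums, and the explanation stays open for the 12 called genes with whole counts and for all those with no near-copy of the same name, such as Sbk1 and RT1-DMa.

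The near-identity of the 2 libraries stood out, with 90.6% of whole-count genes within 1.2-fold. Reads of 1 library divided between 2 columns would give squared differences equal to the counting variance, and the observed value of 1.56 lies above that and above the simulated maximum of 1.05. The spread beyond counting, 3.68%, could come from libraries made from the same or equally treated cells, or from a small response to Aβ. These cannot be told apart, since there is no further library of either group to set that spread against.

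Cell cycle genes lower with Aβ made up 28 of 34 measured members, with a median log2 ratio of -0.069, a shift that the markers of cycling cells Mki67 (ratio 0.993, 0.961 to 1.03) and Top2a (1.01, 0.978 to 1.04) did not share. The trend of the ratio with transcript length is argued against by the list's percentile of 0 among random lists after the trend was removed. A scaling of the libraries shifts all genes alike, so it cannot move the list's percentile among lists matched on level. The percentile of 0 says that the list lay below others of its level, and it is no separate test of scaling. A response of the cells to Aβ is a hypothesis that may hold. It cannot be told apart from a difference between cultures, because there was 1 library per group and cell cycle genes vary together.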
